A study of Mus musculus with 36 samples.

How the data were processed

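RNA newly transcribed in mouse NIH-3T3 fibroblasts was measured on 36 Affymetrix arrays, 3 for each of 12 groups, after labelling with 4-thiouridine (4sU), a nucleoside that cells build into the RNA they make while it is present. The groups cross 3 treatments (fresh medium with mock, with IFN alpha or with IFN gamma, each interferon at 100 U/ml) with 4 labelling windows counted from the medium change: 0-30 min, 30-60 min and 150-180 min at 500 µM 4sU, and 0-60 min at 200 µM. The labels number the arrays of each group but do not say that they are separate cultures, so the p-values measure only the spread between arrays. Arrays give no counts; their number per group limits the precision, and so do the spread between arrays and the signal over background.

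The deposited table holds log2 values for 45101 probe sets, made by the authors with GCRMA per the submitters' processing notes, version not given in the sources used here. The values ran from 1.34 to 14.82 and the median of an array from 3.13 to 3.27, in the range of a log2 scale, and they were used without a further transformation or scaling. No column lacked a sample, and no array of a group duplicated another. Gene symbols came from the annotation of the series' own probes: 34945 probe sets had 1 symbol, 932 had several and 9160 had none, and 64 control probe sets were left out. Of the probe sets with 1 symbol, 34741 matched a gene ID of the GRCm38.p6 gene table, which was used for names only, and 0 symbols had to be updated. No genome build is given in the sources used here, so no coordinates are printed.

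A probe set was kept where its log2 value passed 4 in at least 3 arrays (21874 probe sets, named or not), and each gene was represented by its kept probe set with the highest mean, which left 9549 genes; the 8433 other probe sets of these genes entered only as an alternative. Group means of all 36 arrays were fitted in limma 3.58.1 (R 4.3.3, with the data.table package, 1.17.8) with lmFit and eBayes with an intensity trend, leaving 24 residual and 6.8 prior degrees of freedom. Each of 19 comparisons was a contrast of group means: each interferon against mock and IFN alpha against IFN gamma within each window, the change of each interferon's response between consecutive 30 min windows (a difference of differences), and mock between windows. Limma's moderated test is two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 9549 genes of its comparison. Errors beside log2 differences are standard errors from this fit, with 1 spread per gene over all windows and n = 3 arrays per group.

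Gene lists, 26 with 542 entries of which 496 were named on the array, were fixed before the data were examined, as were the groups, the comparisons, the rule for named genes and most of the alternatives listed here. The 21 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over all 399 tests, and again with a correlation estimated from the data and with fry. Members were also counted with the Benjamini-Hochberg adjustment over the list alone. A list result says how its members moved against all other genes, not that the list's process changed.

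The rule for named genes took, in each interferon against mock comparison, a fixed panel (which included Irf1, Socs1, Irf9, Ifit1, Isg15, Mx1, Usp18, Gbp2, Igtp, Tap1, Cxcl10, Cxcl9, Ciita, Fos and Actb where measured), the 10 largest rises and the 5 largest falls among called genes with every treated array beyond every mock array and a mean log2 of at least 6 in the higher group, and up to 4 called members per list with the largest change. Other comparisons took the 5 largest in each direction and the list members. Isg15 and Ciita had no tested probe set with a single symbol and are not reported.

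A set of further analyses used the same fit. Calls shared between comparisons were counted beside the number expected from the product of their shares, and, since IFN alpha and IFN gamma were set against the same mock arrays, beside 20 draws of simulated unchanged groups compared with those arrays. The response over 0-60 min was set against the log2 of the mean fold change of the 0-30 and 30-60 min windows for 59 genes, with a two-sided sign-flip permutation test of 100000 resamples. Group labels were re-split in every way for 3 against 3 arrays (10 splits), or in 100 drawn ways for the responses between windows.

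Alternatives were no filter, a filter at log2 6, log2 after adding 16, quantile normalization, a shift of arrays to a common median, all probe sets, only the arrays of the windows compared, no intensity trend, array weights, a replicate block, a 2-fold minimum, and leaving out each array. Chosen after seeing the data were a replicate block within windows for the responses between windows, the replicate block in the list tests, the block with only the arrays of the windows compared, leaving out mock 0-60 min array 1, and leaving out all 3 first arrays of the 0-60 min window. The estimation of array weights stopped before it converged, so those values are of little use. Figures and the remaining tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

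The procedure was tested on simulated data with the spread of each window's arrays, 9549 genes and 200 of them changed. At a log2 change of 1, IFN alpha against mock recovered 83.6% of the changed genes at 0-30 min, 79.1% at 0-60 min, 82.1% at 30-60 min and 79.1% at 150-180 min, and 50.7% in the change from 0-30 to 30-60 min. At a log2 change of 0.5 it recovered 17.9%, 32.8%, 19.4%, 17.9% and 0%, and at a change of 2 it recovered 100%, 100%, 100%, 97% and 98.5%. Wrong calls made up 3.5%, 65%, 32%, 4.4% and 11% of the calls; the fit takes 1 spread per gene over windows whose arrays vary by different amounts. A fit of only the arrays of the windows compared gave 10%, 11%, 11%, 6.6% and 13%, and at a log2 change of 1 it recovered 91%, 31.3%, 53.7%, 85.1% and 64.2%. The simulated arrays did not keep what arrays of the same number share, which cancels in the real differences. These shares of wrong calls need not hold for the real calls. A simulated list of 20 genes shifted by 0.5 reached camera p from 4.3e-14 to 2.5e-28, against 0.53 to 0.79 without a shift.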

Results

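The data are 36 arrays of newly transcribed RNA from NIH-3T3 cells, an established line of mouse embryo fibroblasts. Cells received fresh medium with mock, IFN alpha or IFN gamma, and RNA made in 1 of 4 windows after the change was labelled with 4sU, separated and hybridised. Each of the 12 groups had 3 arrays, and 9549 genes were tested. Each gene was read from 1 probe set, and for some named genes the other probe sets were not called. Differences are given as log2 with the standard error of the fit, n = 3 arrays in each group. The fit takes 1 spread per gene over all windows, so errors and adjusted p understate the spread where a window's arrays vary more. For many induced genes the mock level lay under the filter at log2 4, so their fold changes are over background and not over a measured level. The same holds between the interferons where the lower group lay under the filter. Ranks by fold change among such genes depend on the background too. Where a pair of adjusted p follows a gene list, the first is camera's with the preset correlation and the second with an estimated one, or with the array numbers as a block where that is said.

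Vim, a fibroblast intermediate filament gene, averaged log2 13.15, and the 18 fibroblast and matrix genes had a median of 10.84. Markers of other cell types were near background: the median of 12 macrophage genes was 2.65, of 8 epithelial genes 2.66, of 8 endothelial genes 2.39, and of 10 adipocyte and muscle genes 2.51. Only Cd14 (6.17) of the macrophage genes and 3 adipocyte and muscle genes, led by Lpl (7.58), passed the filter, and no epithelial or endothelial gene did, the highest being Epcam at 3.2 and Tek at 2.56. Of the MHC class II genes 0 were tested.

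The first principal component of the arrays held 42.1% of the variance and the second 18.7%, followed by 10% and 6.12%. Arrays of a group correlated across genes at r of 0.988 to 0.995 in the 0-30 min window, 0.91 to 0.987 at 0-60 min, 0.97 to 0.986 at 30-60 min and 0.986 to 0.995 at 150-180 min. The median within-group SD was 0.159, 0.334, 0.239 and 0.163 in the same order. Mock 0-60 min array 1 correlated at 0.91 and 0.911 with its mates, which correlated at 0.987 with each other. The log2 difference between its 3′ and 5′ Gapdh probe sets was 2.67, against -0.31 and -0.3 in the mates. For Actb it was 1.33, against 0.81 and 1.18.

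Arrays with the same number in different treatments shared part of their deviation from the group means. Across genes this correlation was above 0.1 in 9 of 9 pairs at 0-30 min, at 0-60 min and at 30-60 min, in 7 of 9 at 150-180 min, and in 35 of 162 pairs between windows. The main fit used no block. Array numbers were also used as a block, and for the first 3 windows the blocked count is given where it differs from the unblocked one by more than 1.5 times. At 150-180 min the numbers do not pair all arrays, so blocked results that use that window are not relied on. The bioC hybridisation control averaged 7.54, 8.98, 9.33 and 7.21 at 0-30, 0-60, 30-60 and 150-180 min.

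**Figure D1:**
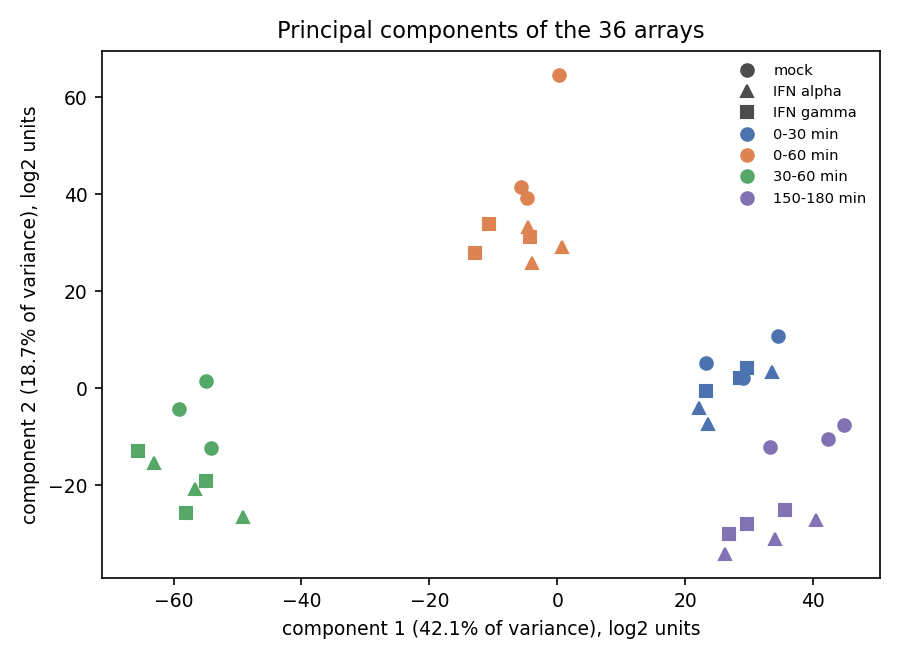
Scores of the 36 arrays on the first and second principal components (log2 units; 42.1% and 18.7% of the variance), coloured by labelling window with 1 marker shape per treatment. Arrays lie by window, and 1 mock array of 0-60 min lies apart.

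Which genes are transcribed within 30 min of IFN alpha was asked by comparing IFN alpha with mock at 0-30 min. Iigp1, a GTPase that acts on the vacuoles of intracellular pathogens, rose most, by log2 4.87 ± 0.36 (29.3-fold, adjusted p = 7.5e-11), over a mock level of 2.89, under the filter. Ifit3 and Ifit1, which act against viral RNA, rose 21.8-fold (log2 4.45 ± 0.4) and 20.2-fold (log2 4.34 ± 0.5). Cxcl10, a chemokine that attracts T cells, rose by 4.45 ± 0.47 and Irf9, a transcription factor of interferon signalling, by 2.81 ± 0.17. Gbp2 (0.92 ± 0.35), Socs1 (1.08 ± 0.34) and Cxcl9 (0.03 ± 0.48) did not pass. In limma 36 genes were higher and 0 lower, with 101 higher and 36 lower at an unadjusted p under 0.05.

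Of 48 tested antiviral genes 17 were higher (25 adjusted over the list alone), among them Rtp4 (3.61 ± 0.54), Oas1a (2.64 ± 0.3) and Mx2 (2.78 ± 0.43), and the list's median was 0.8. Of 11 interferon-inducible GTPases 6 were higher, 8 adjusted over the list alone, with Igtp (3.69 ± 0.29) and Irgm2 (3.68 ± 0.24) beside Iigp1. Both lists kept camera calls with an estimated correlation, as did MHC class I (2 of 13, Tap1 2.5 ± 0.28 and Psmb9 1.07 ± 0.21), interferon signalling (3 of 19, including Irf1 at 2.15 ± 0.19) and feedback inhibitors (1 of 14, Usp18 at 2.16 ± 0.5). The Usp18 call ended in 5 and that of Psmb9 in 2 of 6 fits with 1 array left out. Chemokines were called higher by camera at adjusted p = 0.016 (0.19 with an estimated correlation) although 1 of 18 passed and the median was -0.01, against a mean of 0.27. Ribosomal protein genes (adjusted p = 0.005, 0.44 with an estimated correlation) and oxidative phosphorylation genes (5.2e-05, then 0.28) were called lower without a single gene passing.

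The same window with IFN gamma asked which genes answer the type II interferon first. Irf1, a transcription factor that drives many later interferon genes, rose 35.2-fold (log2 5.14 ± 0.19, adjusted p = 4.4e-19). Iigp1 rose 72.7-fold (6.18 ± 0.36), Igtp 38.3-fold (5.26 ± 0.29) and Irgm2 37.2-fold (5.22 ± 0.24). Socs1 and Socs3, inhibitors of JAK-STAT signalling, rose by 2.82 ± 0.34 and 2.8 ± 0.15, and Cxcl9 by 3.37 ± 0.48. The 1 other probe set of Cxcl9 was not called. Ifit1 (0.48 ± 0.5), Mx1 (0.05 ± 0.42) and Usp18 (0.31 ± 0.5) did not pass. These errors come from the fit over all windows. Within this window the Ifit1 arrays lay apart, at 7.78 (SD 0.03) with IFN gamma and 7.3 (SD 0.09) in mock. In all, 72 genes were higher and 4 lower, and with the array numbers as a block 107 and 18 (125 in all), and with this window's arrays alone 94 and 20. The count fell to 50, 47 and 48 without mock array 2, mock array 3 or IFN gamma array 1.

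Of the GTPases 8 of 11 were higher (9 adjusted over the list alone), and Tap1 (3.7 ± 0.28) and Psmb9 (1.9 ± 0.21), which carry and cut the peptides shown on MHC class I, were the 2 higher of that list. The antiviral list had 2 higher of 48, Trim21 (2.04 ± 0.26) and Trim25, and a median of 0.18; its camera call at adjusted p = 7.3e-08 became 0.25 with an estimated correlation. Feedback inhibitors had 3 of 14 higher, adding Cish (1.86 ± 0.27), and signalling genes 2 of 19. Of 18 chemokines and cytokines 5 were higher and 1 lower, camera adjusted p = 1.4e-05. NF-kB targets had 2 of 15 higher (Tnfaip2 1.58 ± 0.16), camera adjusted p = 0.016 and 0.087 with an estimated correlation. Among the fallers Hes1, a repressor downstream of Notch, was lower by 1.23 ± 0.24 (adjusted p = 0.0038), and Lif and Id4 were lower by 1.22 and 0.65. Leaving out an array ended these calls in 1, 5 and 4 of 6 fits. The 2 other probe sets of Id4 were not called. TGF-beta and BMP targets (adjusted p = 0.12, 0.047 with the block) had Id4 as the only gene past. Ribosomal protein genes (0.066, then 0.047 with the block) and oxidative phosphorylation genes (0.0012, then 0.41 with an estimated correlation) had 0 past and were lower.

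The 30-60 min window asked what is being transcribed in the second part of the first hour. With IFN alpha, Ifit1 rose 504-fold (log2 8.98 ± 0.5, adjusted p = 4.7e-15), Ifit3 262-fold (8.03 ± 0.4), Cxcl10 163-fold (7.35 ± 0.47) and Usp18 104-fold (6.7 ± 0.5); Usp18 restrains type I interferon signalling. Mx1, an antiviral dynamin-like GTPase, rose by 5.63 ± 0.42 and Irf1 by 4.09 ± 0.19. Mock was low for Ifit1 in this window, at 4.05 against 7.3 at 0-30 min and 6.64 at 150-180 min. With IFN alpha Ifit1 was at 13.03 here and at 13.08 at 150-180 min, where its rise was 87.1-fold. In all, 229 genes were higher and 18 lower; with the block 351 were higher and 157 lower (508 in all), so falls were few without the block and not with it. In the simulation of this window, which did not keep what arrays of the same number share, 32% of the calls were wrong. A fit of this window's arrays alone called 194 genes higher and 4 lower, 186 of them also among the 247.

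Of the antiviral genes 42 of 48 were higher, with a median of 3.45, and of the GTPases 9 of 11, with a median of 5.09; over each list alone the counts were 45 and 9. MHC class I genes were higher for 10 of 13, among them Tap1 (4.93 ± 0.28), Tapbp (2.31 ± 0.3) and B2m (1.76 ± 0.21). Signalling genes passed in 4 of 19 (Irf1, Stat2, Irf9 and Irf7) and feedback inhibitors in 4 of 14. Chemokines (4 of 18, adjusted p = 5.6e-04, 0.055 with an estimated correlation) and NF-kB targets (2 of 15, adjusted p = 0.0052, 0.052 estimated) were also called. Fas, Hk2 and Mcm6 were higher members of the p53, glycolysis and cell cycle lists, none of which was called. Agfg2 (-0.9 ± 0.22), Foxk1 (-0.77 ± 0.21), Dgat1 (-0.72 ± 0.18), Ephb3 (-0.7 ± 0.19) and Tgfbrap1 (-0.68 ± 0.19) were the largest falls, and every one lost its call in some fits with 1 array left out. The other probe sets of Agfg2, Dgat1 and Tgfbrap1, 1 each, were not called. Short-lived non-coding host genes were called with the block (adjusted p = 0.07, then 0.015), with 0 of 13 genes past.

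IFN gamma at 30-60 min raised Iigp1 251-fold (7.97 ± 0.36), Igtp 249-fold (7.96 ± 0.29) and Cxcl9, a T-cell chemokine, 182-fold (7.51 ± 0.48). Irf1 was 57.9-fold higher (5.86 ± 0.19, adjusted p = 6.8e-21), Tap1 higher by 5.63 ± 0.28 and Gbp2 by 5.44 ± 0.35. Usp18 (0.26 ± 0.5) and Mx1 (0.12 ± 0.42) again did not pass, while Ifit1 did (1.96 ± 0.5, adjusted p = 0.012). The Ifit1 level with IFN gamma was lower than at 0-30 min, at 6.01 against 7.78, and mock was lower still, at 4.05 against 7.3. So this call came with a lower mock level and not with a higher level under IFN gamma. Lif fell by 2.11 ± 0.29, Hes1 by 1.9 ± 0.24 and Dusp1, a MAP kinase phosphatase, by 1.74 ± 0.23, beside Lhx9 (-2.19 ± 0.32) and Ramp3 (-1.92 ± 0.24). The control gene Actb (-0.11 ± 0.12) and the immediate-early gene Fos (0.64 ± 0.23, adjusted p = 0.11) did not pass here or in any other comparison of an interferon with mock. In all, 365 genes were higher and 197 lower. With the block 549 were higher and 612 lower (1161 in all), so the majority changed direction, and the window's own arrays alone gave 315 higher and 148 lower (463 in all), of which 399 were shared.

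Antiviral genes passed in 20 of 48 (median 0.5, camera adjusted p = 0.039 with an estimated correlation), GTPases in 9 of 11 (median 5.35) and MHC class I in 7 of 13. NF-kB targets rose in 5 of 15, 7 adjusted over the list alone, among them Tnfaip2 (3.37 ± 0.16), Icam1 (2.49 ± 0.16) and Sod2 (2.26 ± 0.2), with camera adjusted p = 6.1e-06. Feedback inhibitors passed in 4 of 14, led by Socs3 (3.45 ± 0.15), and signalling genes in 5 of 19. Immediate-early genes moved both ways, 3 higher and 7 lower of 35 (5 and 12 adjusted over the list alone, adjusted p = 0.095): Zfp36 was higher by 1.33 ± 0.24, while Nr4a3 (-1.12 ± 0.2) and Nr4a2 (-1.25 ± 0.24) were lower. Chemokines and cytokines had 6 higher and 2 lower (adjusted p = 6.6e-04, 0.057 estimated).

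Smaller groups held a few further genes with IFN gamma at 30-60 min. Bnip3, a mitophagy receptor, and Hk2, a hexokinase, were above mock by 3.25 ± 0.29 and 2.25 ± 0.11, with Pfkfb3 lower, and the glycolysis and hypoxia list was called higher (adjusted p = 0.022, 0.075 estimated). Mock itself was low for Bnip3 in this window, at 4.82 against 8.72 at 0-30 min and 8.64 at 150-180 min. The glycolysis list was also lower in mock here than at 0-30 min. Fas rose by 1.62 ± 0.21 and Trib3 by 1.47 ± 0.19 while the p53 (0.79) and ATF4 (0.59) lists were not called. TGF-beta and BMP targets were called lower, with 3 of 13 lower and over the list alone 3 higher and 7 lower (adjusted p = 0.038, 0.18 estimated); Id4 fell by 1.23 ± 0.16. Sterol synthesis genes (1 of 15 lower, adjusted p = 0.027, 0.099 estimated) and clock genes (0 of 15, adjusted p = 0.049, 0.075 estimated) were called lower too. Ccnd1, cyclin D1, fell by 1 ± 0.18, and the cell cycle list passed only with the block (0.069, then 0.047), as did heat shock genes (0.061, then 0.022). SRF and YAP targets had Acta2 higher and Ankrd1 lower (0.4), and fibroblast genes Vim higher and Lox lower.

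**Figure D2:**
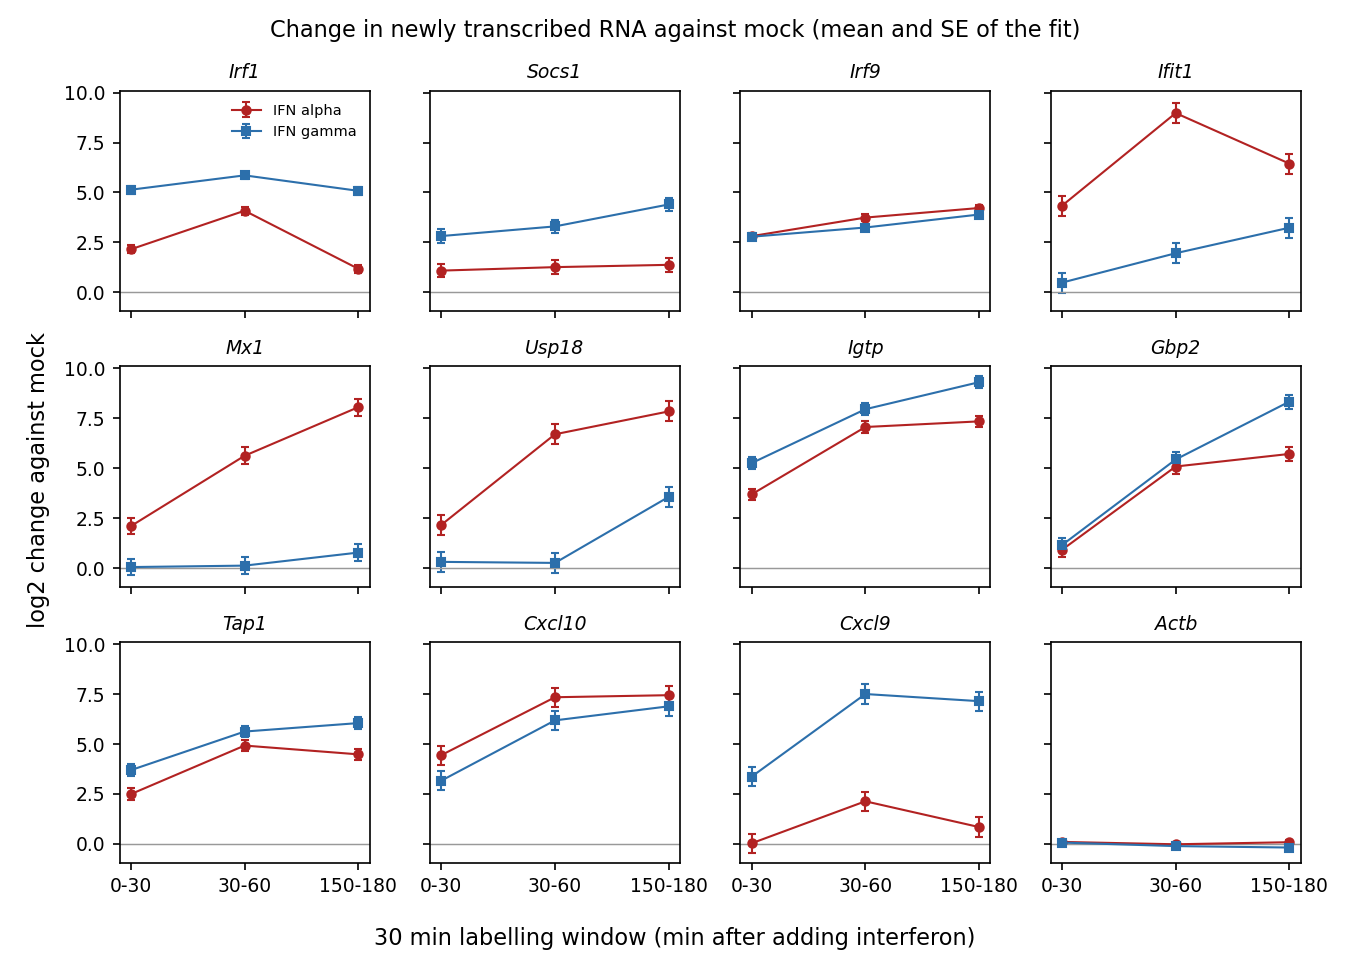
Log2 change against mock in the 3 windows of 30 min (horizontal axis) for 12 genes of the fixed panel, IFN alpha in red and IFN gamma in blue, with standard errors of the fit and 3 arrays per group. Irf1 was 5.14 above mock at 0-30 min and 5.08 at 150-180 min with IFN gamma, and 2.15 and 1.17 with IFN alpha.

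After 150-180 min of IFN alpha the question was which genes are still, or newly, transcribed. Oasl2 was 372-fold higher (8.54 ± 0.45, adjusted p = 6.7e-16), Ifit3 313-fold (8.29 ± 0.4), Rsad2, which encodes the antiviral enzyme viperin, 280-fold (8.13 ± 0.59) and Mx1 267-fold (8.06 ± 0.42). Usp18 was higher by 7.85 ± 0.5, and Irf1 by 1.17 ± 0.19. Cxcl9 (0.84 ± 0.48) did not pass. In all, 246 genes were higher and 11 lower, and the window's own arrays gave 328 higher and 64 lower (392 in all), including 251 of these 257. The 11 lower genes became 30 without a filter, 25 after adding 16 and 33 without mock 0-60 min array 1, and 5 with the filter at log2 6.

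Rises covered 46 of 48 antiviral genes (median 4.54), with GTPases past in 10 of 11 (6.27) and MHC class I genes in 13 of 13 (1.81), Psmb10 by 3.79 ± 0.3 and Tapbp by 3.18 ± 0.3. Signalling genes had 7 of 19 higher, among them Irf7 (4.09 ± 0.28) and Nlrc5, the transactivator of MHC class I genes (2.91 ± 0.13). Chemokines and cytokines had 6 of 18 higher, with Ccl2 at 1.84 ± 0.14 and Il15 at 1.94 ± 0.29. Each of these calls held with an estimated correlation. Feedback inhibitors were past in 3 of 14 and not called (adjusted p = 0.061), and NF-kB targets had only Vcam1 (0.75). Kif26b (-0.74), Wwc1 (-0.66), Chst11 (-0.66) and Gpam (-0.49) fell, each losing its call in 3 to 5 of 6 fits with 1 array left out.

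IFN gamma at 150-180 min gave the largest rise of any comparison with mock: Iigp1 was 1240-fold higher (10.28 ± 0.36, adjusted p = 1.7e-20), followed by the guanylate-binding protein Gbp6 (9.38 ± 0.31) and Igtp (9.31 ± 0.29). Their mock levels of 2.83, 3.13 and 3.51 lay under the filter. Cd274, which encodes the T-cell inhibitor PD-L1, rose 245-fold (7.94 ± 0.39) and Nlrc5 39.1-fold (5.29 ± 0.13). Irf1 was still 33.8-fold higher (5.08 ± 0.19). Usp18 passed in this window, 11.8-fold higher (3.56 ± 0.5), and Mx1 did not (0.78 ± 0.42). Hes1 and Fam110c fell by 1.79, Cthrc1 by 1.52 ± 0.21, the cytokine gene Tslp by 1.48 ± 0.25 and Lxn by 1.4 ± 0.17. In all, 417 genes were higher and 147 lower; the window's own arrays gave 586 higher and 481 lower (1067 in all), with 541 shared, so the lower genes more than tripled.

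Antiviral genes rose in 39 of 48 (median 2.23), GTPases in 11 of 11 (7.96) and MHC class I genes in 13 of 13 (2.74), with Psmb9 at 5.58 ± 0.21 and Tap1 at 6.05 ± 0.28. Signalling genes passed in 9 of 19 and feedback inhibitors in 5 of 14, led by Socs1 (4.4 ± 0.34). Chemokines and cytokines had 8 of 18 higher, among them Ccl8 (2.91 ± 0.24) and Cxcl10 (6.89 ± 0.47). Hk2 rose by 2.48 ± 0.11, and the glycolysis and hypoxia list kept its call with an estimated correlation (adjusted p = 7.1e-04, then 0.011). NF-kB targets had 3 of 15 higher (adjusted p = 0.0063, 0.055 estimated). Immediate-early genes had 5 higher and 1 lower (0.15), among them Atf3 higher by 1.69 ± 0.17 and Egr3 lower by 0.98 ± 0.17. Oxidative phosphorylation genes were called lower with 0 of 31 past (adjusted p = 0.038, 0.61 estimated). Single genes passed in the p53 (Fas 2.09 ± 0.21), heat shock (Hsph1), SRF and YAP (Ajuba) and TGF-beta (Id4 -0.99 ± 0.16) lists, with 3 clock genes (Per2 and Dbp lower, Nfil3 higher) and 2 fibroblast genes (Postn and S100a4, lower), and none of these lists was called; Cd14 (-0.88 ± 0.19) and Lpl (-1.04 ± 0.25) were lower.

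The 0-60 min window covers the whole first hour at 200 µM 4sU. Its arrays varied most, with a median within-group SD of 0.334, and the errors, taken over all windows, understate that spread. Igtp rose 104-fold with IFN alpha (6.71 ± 0.29), Usp18 78.1-fold (6.29 ± 0.5) and Ifit1 56.7-fold (5.83 ± 0.5), and Irf1 rose by 3.41 ± 0.19. Antiviral genes were higher in 39 of 48 (median 2.31), GTPases in 9 of 11 (4.09), MHC class I in 8 of 13, signalling in 4 of 19, feedback inhibitors in 5 of 14 and chemokines in 3 of 18 (adjusted p = 0.0015, 0.075 estimated). NF-kB targets, with Tnfaip2 higher by 1.21 ± 0.16, were called with the block (0.059, then 0.032). Ribosomal protein genes (adjusted p = 8.0e-04, 0.34 estimated) and oxidative phosphorylation genes (0.041, 0.62 estimated) were called lower without a gene past. In all, 182 genes were higher and 7 lower, with 359 and 100 with the block (459 in all). The 7 lower genes became 62 without a filter and 22 with arrays shifted to a common median. Leaving out mock array 2 or 3 gave 803 and 725 genes, which leaves mock array 1, with its deviating Gapdh difference, among the mock arrays kept. In the simulation, which did not keep what arrays of the same number share, 65% of calls in this window were wrong. The window's own arrays alone called 63 genes, all higher and each among the 189. With the block as well, those arrays called 83 genes higher and 0 lower. In the simulation the fit of the window's own arrays recovered 31.3% of changes of log2 1, so smaller changes named for this window are uncertain.

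**Figure D3:**
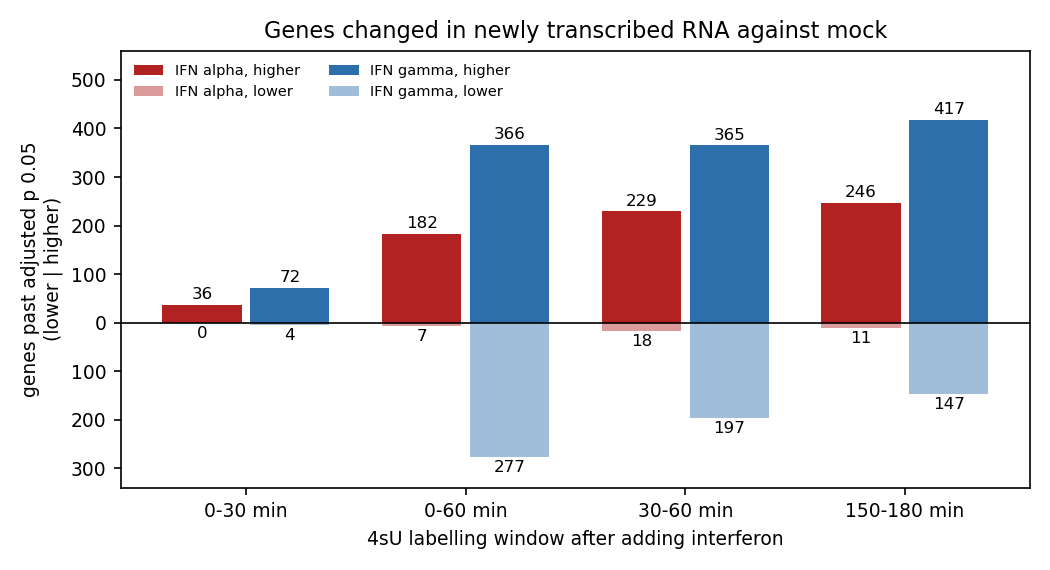
Number of genes called higher and lower against mock (Benjamini-Hochberg adjusted p under 0.05 in limma, of 9549 tested) for each interferon and labelling window. Genes called lower with IFN alpha number 0 to 18, and with IFN gamma 4 to 277, but with the array numbers as a block 1, 100 and 157 with IFN alpha and 18, 1129 and 612 with IFN gamma at 0-30, 0-60 and 30-60 min. With the block and only each window's own arrays, 5, 0 and 354 were lower with IFN alpha, and 45, 46 and 904 with IFN gamma.

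With IFN gamma at 0-60 min Igtp rose 168-fold (7.4 ± 0.29), Cxcl9 75.9-fold (6.25 ± 0.48), Tap1 by 5.42 ± 0.28 and Irf1 by 4.73 ± 0.19. The 1 other probe set of Cxcl9 was not called. Edn1, the gene of endothelin-1, fell 4.65-fold (-2.22 ± 0.2, adjusted p = 6.3e-10), the clock repressor Nr1d1 by 2.04 ± 0.25, Hes1 by 1.92 ± 0.24 and Rgs4 by 1.63 ± 0.13. The 2 other probe sets of Rgs4 were not called. Ccnd1 fell by 1.4 ± 0.18 and Id4 by 1.22 ± 0.16. In all, 366 genes were higher and 277 lower, while with the block 820 were higher and 1129 lower (1949 in all) and without a filter 326 and 328, so which direction prevailed depended on the setting. The window's own arrays gave 106 higher and 14 lower, each among the 643, so most of the 277 falls were not called there. With the block as well, those arrays gave 159 higher and 46 lower, so most of the 1129 falls were not called there either. Leaving out IFN gamma array 2 gave 419, and leaving out mock array 2 or 3 gave 1670 and 1466. Without the 3 first arrays of the window, among them the mock array with the deviating Gapdh difference, 288 were higher and 151 lower.

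Antiviral genes had 15 higher and 1 lower of 48 (median 0.3, adjusted p = 3.1e-08, 0.23 estimated), GTPases 9 of 11 higher, MHC class I 5 of 13, signalling 5 of 19 and feedback inhibitors 4 of 14. NF-kB targets were higher in 5 of 15 (Tnfaip2 2.94 ± 0.16, Icam1 2.34 ± 0.16), with adjusted p = 7.5e-05. Chemokines and cytokines had 6 higher and 2 lower (adjusted p = 4.6e-04, 0.052 estimated). ATF4 and unfolded protein response genes (4 of 21 lower, adjusted p = 0.0013, 0.087 estimated) and sterol synthesis genes (3 of 15 lower, adjusted p = 0.0099, 0.056 estimated) were called lower, and immediate-early genes (2 higher, 6 lower; 0.051, 0.045 with the block) and TGF-beta targets (0.089, then 0.045) with the block. SRF and YAP targets had 3 of 15 lower (0.36), p53 targets 3 higher (0.83), clock genes 2 lower (0.073) and the glycolysis list Bnip3 and Hk2 higher, without a call.

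IFN alpha was set against IFN gamma in each window to ask which genes the interferons drive differently. At 0-30 min Ifit3 was 19.2-fold higher with IFN alpha (4.26 ± 0.4), Ifit1 higher by 3.85 ± 0.5 and Helz2 by 1.88 ± 0.2. Irf1 was 7.91-fold higher with IFN gamma (2.98 ± 0.19, adjusted p = 1.3e-12), as were Rnd1 by 2.55 ± 0.22, Socs3 by 2.24 ± 0.15 and Ggct by 2.11 ± 0.29. There were 18 genes higher and 50 lower with IFN alpha, and 41 and 76 with the block (117 in all). Without IFN alpha array 3 or IFN gamma array 1 the 68 calls fell to 44 and 43. Antiviral genes were higher with IFN alpha in 12 of 48, GTPases lower in 3 of 11 (adjusted p = 1.4e-12), feedback inhibitors lower in 3 of 14 and NF-kB targets in 2 of 15 (adjusted p = 0.0012). MHC class I genes were called higher with IFN alpha (adjusted p = 0.0099, 0.27 estimated) while Tap1 was lower, and short-lived non-coding host genes were called with the block (0.068, then 0.036).

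At 30-60 min Ifit3 was 148-fold higher with IFN alpha (7.21 ± 0.4), Ifit1 by 7.02 ± 0.5 and Mx2 by 6.55 ± 0.43, and Cxcl9 was 41.4-fold higher with IFN gamma (log2 -5.37 ± 0.48 as IFN alpha minus IFN gamma), beside the eotaxin gene Ccl11 (3.28 ± 0.24) and Il18rap (3.27 ± 0.22). With IFN gamma Ifit3 (3.79) and Mx2 (2.54) lay under the filter, so these differences are over background. In all, 284 genes were higher and 260 lower with IFN alpha, with 549 and 437 with the block (986 in all) and 257 and 270 after quantile normalization. Antiviral genes were higher in 40 of 48 (median 2.25) and NF-kB targets lower in 3 of 15, Icam1 by 2.47 ± 0.16 (list adjusted p = 0.0042, 0.045 estimated). GTPases were called lower without a gene past (0.028, 0.49 estimated), and MHC class I higher with 3 higher and 1 lower (0.026, 0.35 estimated). Calls lost with an estimated correlation were also immediate-early genes (5 higher, 2 lower; 0.032, 0.6), sterol synthesis (0 past; 0.024, 0.092), heat shock (2 higher; 0.0033, 0.056), cell cycle (3 higher; 0.029, 0.4) and glycolysis (1 higher, 3 lower; 0.041, 0.11, and 0.12 with the block). Hk2 was lower by 1.59 ± 0.11 and Bnip3 by 2.52 ± 0.29. TGF-beta targets passed with the block (0.14, then 0.043).

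At 150-180 min Mx1 was 156-fold higher with IFN alpha (7.28 ± 0.42) and Rsad2 by 6.5 ± 0.59, and with IFN gamma Cxcl9 was 79.2-fold higher (6.31 ± 0.48), Fst, the gene of follistatin, 17.4-fold (4.12 ± 0.18) and Irf1 by 3.91 ± 0.19. Mx1 with IFN gamma (3.79) and Cxcl9 with IFN alpha (3.2) lay under the filter, so their fold changes are over background. In all, 181 genes were higher and 267 lower with IFN alpha; the window's own arrays gave 349 and 424 (773 in all). Antiviral genes were higher in 36 of 48 (median 1.89), while GTPases were lower in 8 of 11 (median -1.81) and MHC class I genes in 7 of 13 (-0.74), with Gbp6 lower by 2.91 ± 0.31 and Psmb9 by 2.56 ± 0.21. The glycolysis list was lower (2 of 17, adjusted p = 2.2e-04), Hk2 by 2.37 ± 0.11. Signalling genes had 1 higher and 5 lower (0.0013, 0.087 estimated), feedback inhibitors 1 and 4 (0.0085, 0.065), chemokines 1 and 5 (0.0065, 0.13) and NF-kB targets 3 lower (0.012, 0.075).

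At 0-60 min Usp18 was 42.1-fold higher with IFN alpha (5.39 ± 0.5) and Cxcl9 17.1-fold higher with IFN gamma (4.1 ± 0.48), as were Ccl11 (3.15 ± 0.24) and Tifa (2.87 ± 0.32). These errors come from the fit over all windows. Within this window the SD with IFN alpha and IFN gamma was 0.98 and 1.53 for Usp18 and 1.9 and 0.97 for Cxcl9. Usp18 with IFN gamma (3.03) lay under the filter, so its fold change is over background, and the 1 other probe set of Cxcl9 was not called. In all, 225 genes were higher and 158 lower with IFN alpha, with 618 and 294 with the block (912 in all), and 28 higher and 48 lower from this window's arrays alone, where the majority turned. The higher share of 58.7% became 48.1% after quantile normalization and 46% after a shift to a common median. Antiviral genes were higher in 39 of 48 and NF-kB targets lower in 3 of 15 (adjusted p = 1.7e-04), and sterol synthesis genes were called higher (1 of 15, adjusted p = 0.002). ATF4 targets (3 of 21 higher, adjusted p = 0.0016, 0.092 estimated) and immediate-early genes (2 of 35 higher, 0.0075, 0.51 estimated) lost their calls, and feedback inhibitors passed with the block (0.088, then 0.026).

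**Figure D4:**
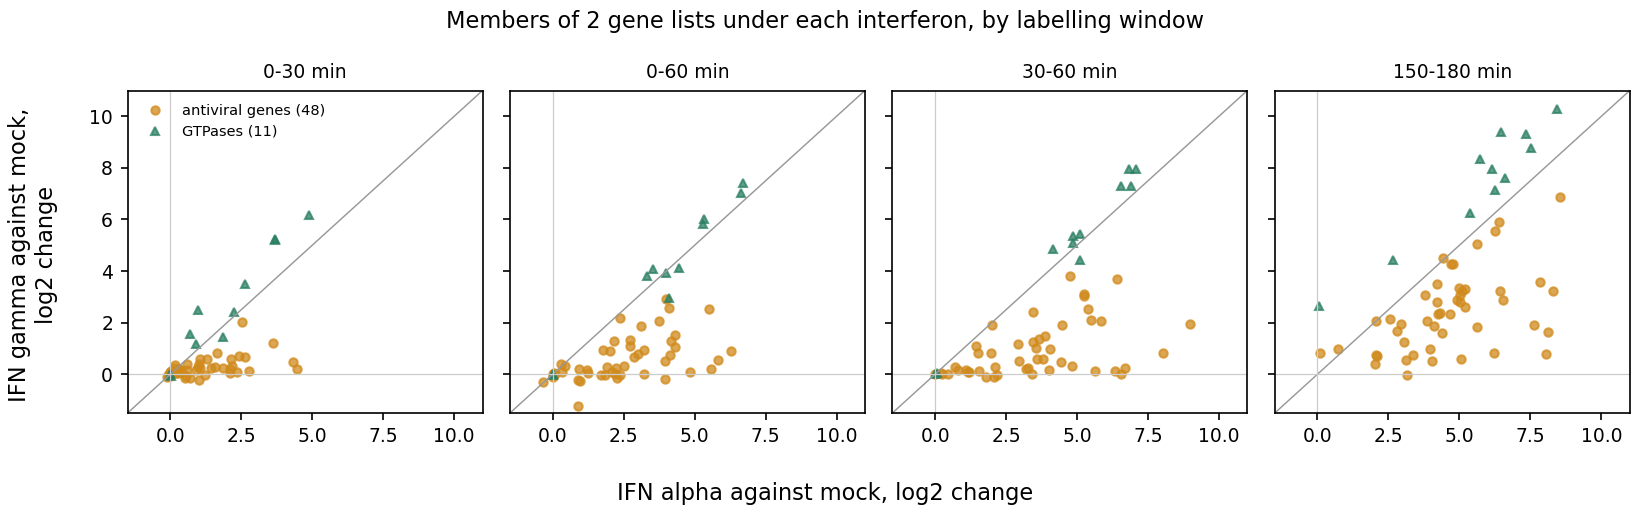
Log2 change against mock of each of 48 antiviral genes and 11 interferon-inducible GTPases, IFN alpha on the horizontal and IFN gamma on the vertical axis, in 1 panel per labelling window with a line of equal change. At 150-180 min the antiviral genes had medians of 4.54 with IFN alpha and 2.23 with IFN gamma, and the GTPases 6.27 and 7.96.

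Changes of a response between windows asked which genes answer early or late. From 0-30 to 30-60 min the IFN alpha response of Parp9 grew by 5.26 ± 0.37 (adjusted p = 3.1e-11), of Parp14 by 5.04 ± 0.38 and of Usp18 by 4.54 ± 0.71. A response is a difference from mock, so it also moves with the mock level: that of Ifit1 grew by 4.64 ± 0.71 with mock falling from 7.3 to 4.05 and IFN alpha rising from 11.63 to 13.03. The response grew for 121 genes and shrank for 4 (190 and 22 with the block), and of these 4 Snx8, Ak4 and Agfg2 lost the call in 6 or more of 12 fits with 1 array left out. It grew for 34 of 48 antiviral genes (median 2.35), 9 of 11 GTPases and 6 of 13 MHC class I genes. Feedback inhibitors had 3 of 14 growing (adjusted p = 5.1e-04) and NF-kB targets Tnfaip2 (list 0.0033). Calls lost with an estimated correlation were signalling (2 of 19; 0.0038, 0.12), chemokines (1 of 18; 0.02, 0.21), ribosomal (0.0048, 0.44), oxidative phosphorylation (0.0045, 0.49) and short-lived non-coding genes (0.013, 0.12), the last 3 with 0 genes past.

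From 30-60 to 150-180 min the IFN alpha response of Oas2, a sensor of double-stranded RNA, grew by 5.02 ± 0.16 (adjusted p = 2.9e-21) and of Ifih1, which encodes the RNA sensor MDA5, by 3.5 ± 0.23. It shrank for Irf1 by 2.91 ± 0.27, for Socs3 by 1.99 ± 0.21 and for Tnfaip2 by 1.52 ± 0.23. It grew for 41 genes and shrank for 4; with a block within windows, whose numbers do not pair all arrays at 150-180 min, it grew for 74 and shrank for 51. Among the 41 were 13 of 48 antiviral genes (22 adjusted over the list alone, with 3 lower), 2 of 11 GTPases and 3 of 13 MHC class I genes. Feedback inhibitors (1 lower; 0.018, 0.096 estimated, 0.051 with the block), NF-kB targets (1 lower; 0.029, 0.12), signalling (2 higher, 1 lower; 0.02, 0.23), chemokines (1 higher; 0.019, 0.2) and oxidative phosphorylation genes (0 past, lower; 0.03, 0.6) lost their calls, and ribosomal genes passed with the block (0.066, then 0.048).

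From 0-30 to 30-60 min the IFN gamma response of Gbp2 grew by 4.29 ± 0.5, of Cxcl9 by 4.14 ± 0.68 and of Samhd1, a nucleotide hydrolase that restricts retroviruses, by 3.81 ± 0.26. It grew for 121 genes and shrank for 22 (222 and 123 with the block), with Mn1 (-1.5 ± 0.24) and Six4 (-1.34 ± 0.23) among the largest falls. The arrays of these windows alone gave 169 growing and 51 shrinking, and the fit without mock 0-60 min array 1 gave 168 and 59. GTPases grew in 8 of 11 and MHC class I genes in 3 of 13, and NF-kB targets in 3 of 15 (adjusted p = 2.9e-06), with Icam1 at 2.49 ± 0.22. The antiviral list had 7 of 48 past (14 adjusted over the list alone; adjusted p = 1.4e-13, 0.092 estimated). Hk2 grew by 2.05 ± 0.16, the glycolysis list being called at 0.012 (0.053 estimated). Signalling (1 of 19; 0.024, 0.25), sterol (lower; 0.017, 0.075) and immediate-early genes (1 each way; lower, 0.019, 0.56) lost their calls, while TGF-beta (0.14, then 0.041) and oxidative phosphorylation genes (0.074, then 0.042) passed with the block.

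From 30-60 to 150-180 min the IFN gamma response of Nlrc5 grew by 5.28 ± 0.18 (adjusted p = 1.4e-20), of Gbp6 by 4.51 ± 0.44 and of Gbp2b by 4.41 ± 0.15, and it shrank for Icam1 by 2.46 ± 0.22 and for Bnip3 by 2.13 ± 0.41. The change for Bnip3 came from mock, where its level rose from 4.82 to 8.64, while with IFN gamma it rose from 8.071 to 9.755. The response grew for 115 genes and shrank for 67, or for 311 and 234 with the block, whose numbers do not pair all arrays at 150-180 min. Antiviral genes grew in 20 of 48 (32 adjusted over the list alone), GTPases in 9 of 11 and MHC class I genes in 9 of 13 (median 2.2), Tapbpl by 2.5 ± 0.25. Chemokines grew in 4 of 18 (7.9e-05), Ccl2 by 1.75 ± 0.19, and signalling genes in 2 of 19 (3.9e-06). Immediate-early genes (0 past, higher; 5.4e-04, 0.35 estimated) and oxidative phosphorylation genes (0 past, lower; 0.03, 0.6) lost their calls, and sterol (0.07, then 0.048), TGF-beta (0.16, then 0.04) and ribosomal genes (0.069, then 0.049) passed with the block. Of 100 drawn splits, the real one included, 10 to 17 gave at least as many calls as each of these responses; 5 to 12 of them turn the response around in 1 window, so that real effects add up.

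Mock cells were compared between windows to see how transcription moved with time after the medium change, although hybridisation controls differed between the windows too. From 0-30 to 30-60 min 864 genes were higher and 4948 lower, and the median of all genes was -0.52, so lists are given relative to it. The share higher of 15% became 47.5% after quantile normalization and 54.4% after the median shift. Id2, a target of BMP signalling, rose by 2.6 ± 0.19, Tnc by 3.73 ± 0.19 and the SRF target Vcl by 2.47 ± 0.14, while the mitotic kinase gene Plk1 fell by 2.57 ± 0.19 and Msln by 4.78 ± 0.23. TGF-beta targets had a median of 1.97 relative to all genes (10 of 13 higher after the shift), immediate-early genes 0.72 (27 of 35), chemokines 0.7 (11 of 18) and NF-kB targets 0.68 (12 of 15). Cell cycle genes (-0.89, 23 of 29 lower), glycolysis (-0.75, 11 of 17) and sterol synthesis genes (-0.53, 9 of 15) were lower. Calls lost with an estimated correlation were immediate-early (4.2e-09, 0.092), SRF and YAP (0.02, 0.23), short-lived non-coding (0.01, 0.11), ribosomal (1.2e-04, 0.25), oxidative phosphorylation (9.7e-07, 0.19), ATF4 (0.019, 0.23) and feedback genes (0.0086, 0.066; median 0.44 relative to all genes, before that subtraction -0.07 with a mean of 0.17).

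From 30-60 to 150-180 min in mock 5097 genes were higher and 1026 lower, with a median of 0.55; the share higher of 83.2% became 53.3% and 47.3% after the scalings. Npas4 and Arc, known as activity-induced genes of neurons, fell by 4.32 ± 0.24 and 4.04 ± 0.42, and Egr3 fell by 2.54 ± 0.17. Relative to all genes the median of immediate-early genes was -1.56 (34 of 35 lower after the shift), of chemokines -1.43 (12 of 18), of TGF-beta targets -1.08 (9 of 13), of NF-kB targets -1.05 (12 of 15) and of SRF and YAP targets -0.93 (14 of 15), and of cell cycle genes 1.06 (24 of 29 higher). Clock genes were called lower (0.0088, 0.021 estimated), with a median of -0.48 relative to all genes; before that subtraction the median was 0.06 and the mean -0.1. Ribosomal (6.5e-04, 0.32), oxidative phosphorylation (3.2e-06, 0.21), ATF4 (0.036, 0.28), glycolysis (0.02, 0.074) and sterol genes (0.0085, 0.052) lost their calls with an estimated correlation.

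The 0-60 min mock arrays, labelled at 200 µM, were set against the 30-60 min arrays at 500 µM, so window and dose are not separable. There were 4216 genes higher and 1045 lower, the median of all genes was 0.39, and the share higher of 80.1% became 52.9% and 40.5%. The linker histone gene H1f2 was higher by 3.9 ± 0.34 and Nr1d1 by 3.3 ± 0.25, and the non-coding RNA Meg3 was lower by 2.17 ± 0.14. Cell cycle genes were higher (median 0.75 relative to all genes, 21 of 29 after the shift) and short-lived non-coding genes lower (-0.58, 7 of 13), both with an estimated correlation too. Glycolysis (0.016, 0.06), sterol (0.016, 0.075), ATF4 (0.036, 0.28), ribosomal (0.013, 0.51), oxidative phosphorylation (0.0062, 0.51), immediate-early (lower; 0.024, 0.58) and TGF-beta genes (lower; 0.029, 0.15) lost their calls.

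Calls were compared between the interferons and between windows. With both interferons 16 genes were higher at 0-30 min (0.271 expected), 109 at 30-60 min (8.75), 165 at 150-180 min (10.7) and 90 at 0-60 min (6.98), and 0, 6, 4 and 3 lower. In simulations with shared mock arrays the mean number called with both was 0, 4.1, 0.15 and 48 in the same order of windows; these draws did not keep what arrays of the same number share, which cancels in the real differences. At 30-60 min 3 genes moved in opposite directions. All 36 genes higher with IFN alpha at 0-30 min were higher at 30-60 min (0.863 expected) and 35 of them at 150-180 min, and of the 72 genes higher with IFN gamma at 0-30 min 68 were higher at 30-60 min and 62 at 150-180 min. Consecutive windows share no arrays.

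For 59 genes of the antiviral and GTPase lists, the response over 0-60 min was set against that expected from the mean of the 0-30 and 30-60 min fold changes. With IFN alpha the median response was 2.73 against 2.92, with a median difference of -0.17 and 40 genes below (permutation test p = 0.0019). With IFN gamma it was 0.51 against 0.54, with a median difference of -0.06 and 34 below (permutation test p = 0.04). Genes are not independent replicates, and the sign of the difference turned to 0.27 and 0.02 when the mean of the log2 changes was taken instead. With unequal mock levels and doses, these differences cannot tell whether the responses of the windows add up.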

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

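In this part the tests of carry-over, of RNA quality, of a mislabelled array, of 1 deviating mock array, of genes held back by IFN gamma and of splits that part same-numbered arrays in the responses between windows were chosen after the result was seen.

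The response to each interferon differed between consecutive 30 min windows by a test of the difference itself in limma, for 125 genes (IFN alpha, 0-30 to 30-60 min), 45 (IFN alpha, 30-60 to 150-180 min), 143 (IFN gamma, 0-30 to 30-60 min) and 182 (IFN gamma, 30-60 to 150-180 min). Early with IFN alpha the largest gains were Parp9 (log2 5.26), Parp14 (5.04), Ifit1 (4.64), Usp18 (4.54) and Cd274 (4.53), and the losses Agfg2 (-1.31), Cdc25b (-1.23), Snx8 (-1.09) and Ak4 (-0.84). Late with IFN alpha they were Oas2 (5.02), Oas1a (4.74), Gm4951 (3.95), Bst2 (3.53) and Ifih1 (3.5), against Irf1 (-2.91), Socs3 (-1.99), Tnfaip2 (-1.52) and Samhd1 (-1.41). Early with IFN gamma they were Gbp2 (4.29), Cxcl9 (4.14), Samhd1 (3.81), Irgm1 (3.81) and Gbp7 (3.79), against Lhx9 (-1.84), Mn1 (-1.5), Ramp3 (-1.47), Six4 (-1.34) and Dusp1 (-1.31). Late with IFN gamma they were Nlrc5 (5.28), Oasl2 (4.83), Gm4951 (4.66), Gbp6 (4.51) and Gbp2b (4.41), against Cped1 (-2.4), Ifitm5 (-2.4), Bnip3 (-2.13), Serpina3n (-2.12) and Pde4b (-2.09).

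By the share of all drawn splits, chance is not excluded for these 4 counts. Of 100 drawn splits, the real one included, 12 gave at least the 125 genes of the early IFN alpha change (highest other 174), 17 the 45 genes of the late one (254), 13 the 143 genes of the early IFN gamma change (399) and 10 the 182 genes of the late one (376). Of those, 5, 12, 5 and 9 were splits that turn the response around in 1 window, so that the real responses add up instead of being subtracted, and such splits say little about chance. The highest count among other splits that do not turn it was 157, 57, 228 and 180, and of the real counts the 182 genes of the late IFN gamma change alone lie above theirs. These splits do not follow the array numbers, which pair arrays in the first 3 windows. Of the 32 splits that part every same-numbered pair, counted after the result was seen, 7 gave at least 125 genes for the early IFN alpha change (highest other 175) and 8 at least 143 for the early IFN gamma change (399), the real one included; 4 and 4 of these turn the response around, and the highest of the others was 149 and 197. Splits that leave the groups of 1 window as they were still carry a real response, so they do not settle the question, and at 150-180 min the numbers do not pair all arrays. The single genes rest on their own adjusted p and not on these counts.

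Signal also appeared in data outside the gene comparisons, in 3892 tested probe sets without a single gene symbol. Against mock, IFN alpha called 19, 48, 80 and 103 of them at 0-30, 0-60, 30-60 and 150-180 min, and IFN gamma 28, 126, 175 and 222. The largest log2 changes were 5.31, 5.97, 7.11 and 7.86 with IFN alpha and 5.42, 6.79, 8.16 and 9.81 with IFN gamma. With IFN gamma at 30-60 min 128 were higher and 47 lower, and at 150-180 min 207 and 15. Which genes these probe sets measure was not settled here.

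For the comparisons of 3 against 3 arrays the 10 possible splits are too few to reach a share under 0.05. At 0-30 min the real counts against mock were 36 and 76 for IFN alpha and IFN gamma, with 0 and 1 in the highest other split, and at 150-180 min 257 and 564, with 11 and 25. At 30-60 min they were 247 and 562, with 25 and 104. At 0-60 min they were 189 and 643, with 487 and 536, and 5 of the 10 splits gave at least 189 genes. IFN alpha against IFN gamma gave 68, 383, 544 and 448 genes at 0-30, 0-60, 30-60 and 150-180 min, with 0, 139, 167 and 0. Mock between windows gave 5812, 6123 and 5261 genes, with 0, 1 and 1439. In every comparison other than that of 0-60 min with IFN alpha, 1 of 10 splits, the real one, was as large. Within the first 3 windows, where the numbers pair the arrays, the highest split against mock that parts as many pairs as the real one gave 0 and 1 genes at 0-30 min, 1 and 6 at 0-60 min and 1 and 0 at 30-60 min, so the large counts in other splits at 0-60 min came with arrays of the same number on the same side.

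Ribosomal protein and oxidative phosphorylation genes, 60 tested genes with long-lived mRNA, were lower in mock at 30-60 min than at 0-30 min by a median of 1.03, or 0.51 more than all genes, and 0.52 lower than at 150-180 min relative to all genes. Neither list kept its camera call with an estimated correlation, ribosomal protein genes going from adjusted p = 1.2e-04 to 0.25 and oxidative phosphorylation genes from 9.7e-07 to 0.19 (0.32 and 0.21 against 150-180 min), so the pattern itself is uncertain. A difference that follows the bioC level is argued against: 30-60 min arrays numbered 3, whose bioC level of 7.77 was near the 7.54 of the 0-30 min arrays, still had these genes at -0.47, against -0.35 and -0.47 for arrays numbered 1 (10.61) and 2 (9.62). The poly-A control of the arrays numbered 3 was 12.41 in mock, 11.95 with IFN alpha and 12.2 with IFN gamma, against a mean of 7.19 at 0-30 min. Any other batch difference stays open, since window and batch cannot be told apart. Bad mock arrays alone are argued against by the treated arrays, where the difference was -0.4 with IFN alpha and -0.4 with IFN gamma. Carry-over of unlabelled RNA that differs between windows stays open, since immediate-early genes, which are short-lived, were 0.72 higher relative to all genes in the same comparison and the medium change may also raise them; a change in transcription of the 60 genes stays open too.

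Mock 0-60 min array 1 lies apart from its mates, with r of 0.91 and 0.911 against their 0.987. Its 3′ minus 5′ difference for Gapdh was 2.67, outside the -0.57 to 0.73 of the other 35 arrays. For Actb the difference was 1.33, against 0.81 and 1.18 in its mates and up to 2.16 in other arrays. Lower RNA quality or a shorter labelled product in this array would go with the Gapdh value but is not seen for Actb, so it stays open. A mislabelled treated array is argued against, since its antiviral genes lay 0.01 from its mates (lowest IFN alpha array 1.58, lowest IFN gamma array 0.09) and its GTPases at -0.21 (lowest treated array 3.34). No biological explanation was tested, as the design gives none for 1 array of a group.

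With IFN gamma at 30-60 min 197 genes were lower, with a median of -0.76. After the arrays were shifted to a common median the median change was -0.74 and 174 genes were still called. The shift cannot settle an effect of the authors' normalization. The median of all genes in this comparison was -0.054, so the shift could barely move these genes. A single deviating mock array as the whole cause is argued against. With genes called anew without mock array 1, 2 or 3 of this window, 199, 135 and 132 were lower, of which 145, 113 and 119 were among the 197. That these genes rise with time or handling and are held back by IFN gamma stays open: their median change from 0-30 to 30-60 min with IFN alpha was at percentile 100 of 10000 random lists of like expression, yet at -0.25, as high as the highest random list and against a random median of -0.48, it was still below 0. A lower transcription driven by IFN gamma may explain the pattern as well, as a hypothesis found on these data.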

How the results depend on the processing

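The replicate block within windows for the responses between windows, the block in list tests, the block with only the arrays of the windows compared, and the fits without mock 0-60 min array 1 or without all 3 first arrays of 0-60 min were chosen after seeing the data. Counts stand in the order 0-30, 0-60, 30-60 and 150-180 min, and "responses between windows" are IFN alpha early, IFN alpha late, IFN gamma early and IFN gamma late. The cause was not tested where none is given.

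No filter, a filter at log2 6, log2 after adding 16, quantile normalization, a common median and no intensity trend left each count of called genes within 1.5 times its value, but not each direction. The genes lower with IFN alpha went from 7 to 62 at 0-60 min and from 11 to 30 at 150-180 min without a filter, to 22 and 17 at 0-60 min with a common median and quantile normalization, to 3 and 5 with the filter at log2 6, and after adding 16 from 18 to 10 at 30-60 min and to 25 at 150-180 min. Without a filter the genes at 0-60 min with IFN gamma were 326 higher and 328 lower. Of 855 results for single genes, named or examples of a list, 0 reversed under these settings. Calls ended for 60 without a filter, 28 after adding 16, 58 with quantile normalization, 69 with a common median, 22 without the trend and 1 of 820 with the filter at log2 6. With only the arrays of the windows compared 98 ended and 6 were gained, and over the fits without 1 array 547 of 5712 ended and 2 were gained.

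With only the arrays of the windows compared, which lets each window have its own spread, IFN alpha called 63 genes at 0-60 min (63 higher) and 392 at 150-180 min (328 and 64), and IFN gamma 120 (106 and 14) and 1067 (586 and 481). IFN alpha against IFN gamma called 76 (28 and 48) at 0-60 min and 773 at 150-180 min. The IFN alpha late response called 68 (52 growing, 16 shrinking), and the IFN gamma early and late responses 220 (169 and 51) and 274 (167 and 107). This fit recovers fewer simulated changes at 0-60 and 30-60 min and more at 0-30 and 150-180 min. Against mock, the 0-30 and 150-180 min windows, whose arrays vary least, had more calls than in the fit of all arrays, and the 0-60 and 30-60 min windows fewer.

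A 2-fold minimum, by construction, lowered the count with IFN gamma to 251 at 0-60 min, 274 at 30-60 min and 296 at 150-180 min, of IFN alpha against IFN gamma to 191, 267 and 243 in the same windows, of mock between windows to 2708, 3173 and 2083, and of the genes called with IFN gamma at both 30-60 and 150-180 min from 256 to 161. All probe sets, by construction, raised counts with more features tested: IFN alpha gave 74, 310, 437 and 521; IFN gamma 124 at 0-30 min, 950 at 30-60 min and 1029 at 150-180 min; IFN alpha against IFN gamma 111, 579, 910 and 729; the IFN alpha late, IFN gamma early and IFN gamma late responses 88, 235 and 303; and mock 12666, 13818 and 12241.

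With the replicate block, which takes out what same-numbered arrays share, IFN alpha called 459 at 0-60 min, 508 at 30-60 min and 445 at 150-180 min, and IFN gamma 125, 1949, 1161 and 1136. IFN alpha against IFN gamma called 117, 912, 986 and 725. A block within each window gave 212, 125, 345 and 545 for the responses between windows. Counts of lower genes rose with the block by a larger factor than those of higher genes: with IFN alpha 1, 100, 157 and 107 were lower, and with IFN gamma 18, 1129, 612 and 528. At 150-180 min the array numbers pair in only 7 of 9 comparisons, so those counts are not relied on; there the block also brought calls for SRF and YAP targets with IFN alpha (adjusted p = 0.11, then 0.026) and, for IFN alpha against IFN gamma, heat shock (0.087, then 0.026) and cell cycle genes (0.071, then 0.018). The block with only the arrays of the windows compared gave 81, 200 for the interferons at 0-30 min, 83 and 205 at 0-60 min, 801 and 1550 at 30-60 min and 918 and 2176 at 150-180 min, then 205, 136, 1268 and 1061 between the interferons and 478, 405, 773 and 1068 for the responses between windows. Against mock, 5 and 45 of these were lower at 0-30 min, 0 and 46 at 0-60 min, and 354 and 904 at 30-60 min. So most of the blocked falls at 0-60 min were not called with that window's own spread.

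Array weights, whose estimation stopped before convergence, gave 60 with IFN alpha at 0-30 min, 1346 at 30-60 min and 3458 at 150-180 min, and with IFN gamma 181, 415, 1734 and 3881. IFN alpha against IFN gamma gave 191 at 0-30 min, 2085 at 30-60 min and 1350 at 150-180 min, and the responses between windows 641, 2036, 778 and 2487.

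Without 1 array the counts ranged, for IFN alpha, over 25–36, 148–803, 195–237 and 222–256, and for IFN gamma over 47–62, 419–1670, 450–541 and 395–546. IFN alpha against IFN gamma ranged over 43–58, 295–389, 428–470 and 343–381, the responses between windows over 91–116, 38–49, 103–138 and 138–185, and mock over 5082–5468, 5500–5902 and 4623–5317. At 0-60 min IFN alpha gave 803 without mock array 2 and 725 without mock array 3, and IFN gamma 1670 and 1466; without IFN gamma array 2 it gave 419. At 0-30 min IFN gamma gave 50, 47 and 48 without mock array 2, mock array 3 and IFN gamma array 1, and IFN alpha against IFN gamma 44 without IFN alpha array 3 and 43 without IFN gamma array 1. Without mock 0-60 min array 1 in every fit the IFN alpha late, IFN gamma early and IFN gamma late responses gave 68, 227 and 286. Without all 3 first arrays of 0-60 min the counts of that window were 156, 439 and 389, within 1.5 times, but with IFN gamma the lower genes went from 277 to 151. Without mock 0-60 min array 1 the lower genes at 30-60 and 150-180 min went from 18 to 56 and 11 to 33 with IFN alpha, and from 197 to 344 and 147 to 240 with IFN gamma.

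Of 399 list tests 159 were called; an estimated correlation left 87, while fry gave 167, a common median 157, the filter at log2 6 156, the block 177 and the fit without mock 0-60 min array 1 160. For the response over 0-60 min against its windows, the median difference with IFN alpha of -0.17 reversed to 0.27 with the mean of log2 changes (permutation p = 0.0018) and was -0.15 for 11 genes with a mock log2 of at least 6 (permutation p = 0.57), where fewer genes were tested. With IFN gamma the -0.06 turned to 0.02 (permutation p = 0.39) and was -0.06 (permutation p = 0.52). Mock levels and the 4sU dose differed between these windows, so these differences cannot tell whether the responses add up. Signal over background limits these values: genes with a mock level under log2 4 have folds over background, and 24 residual degrees of freedom from 3 arrays per group limit the calls.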

Other observations

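The genes named in this part were picked out after their values were seen, and no further test was run on them.

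Hes1, the Notch-target repressor, was lower with IFN gamma in each window: by 1.23 ± 0.24 at 0-30 min, 1.92 ± 0.24 at 0-60 min, 1.9 ± 0.24 at 30-60 min and 1.79 ± 0.24 at 150-180 min. Id4, an inhibitor of DNA binding induced by BMP signals, was lower by 0.65 ± 0.16, 1.22 ± 0.16, 1.23 ± 0.16 and 0.99 ± 0.16. Hk2, the first enzyme of glycolysis, rose with IFN gamma by 2.25 ± 0.11 at 30-60 min and 2.48 ± 0.11 at 150-180 min, and by 0.66 ± 0.11 with IFN alpha at 30-60 min. Icam1, an adhesion molecule for leukocytes, was higher with IFN gamma by 2.49 ± 0.16 at 30-60 min, and its response shrank by 2.46 ± 0.22 to the last window.

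The response of Irf1 to IFN alpha grew by 1.93 ± 0.27 and then shrank by 2.91 ± 0.27. With IFN gamma it was 5.14, 5.86 and 5.08 at 0-30, 30-60 and 150-180 min, and neither change passed (0.719, adjusted p = 0.34, and -0.775, adjusted p = 0.2); whether the courses differ was not tested. Irf9 answered both interferons alike at 0-30 min, by 2.81 ± 0.17 and 2.78 ± 0.17. Mx1 was higher with IFN alpha by 8.06 ± 0.42 at 150-180 min and did not pass with IFN gamma in any window, the difference between the interferons being 7.28 ± 0.42.

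Correlations across genes between the IFN alpha and IFN gamma responses were 0.59, 0.69, 0.59 and 0.72 at 0-30, 0-60, 30-60 and 150-180 min, against 0.5 in simulations with shared mock arrays only. The covariances were 0.0323, 0.15, 0.137 and 0.228, against 0.012, 0.057, 0.032 and 0.014. Genes are not independent replicates, and 3 mock arrays cannot be divided into separate controls of at least 2 each, so what the shared controls add to these values is not settled. The draws also did not keep what arrays of the same number share, which cancels in the real differences and not in the draws. The highest of 20 simulated draws called 0, 66, 9 and 1 genes with both interferons.

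The poly-A control averaged log2 7.19, 10.73, 9.49 and 8.22 at 0-30, 0-60, 30-60 and 150-180 min, so the windows differ in spiked controls as well as in bioC. Comparisons of an interferon with mock lie within a window, where bioC still ranged from 7.77 to 10.61 by array number at 30-60 min.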
